A study of Mus musculus with 31 samples.

How the data were processed

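Transcript levels in mouse preoptic tissue and the bed nucleus of stria terminalis (BNST) were measured on 31 single-colour Illumina bead arrays, each hybridised with biotin-labelled material made from total RNA. The labels call the arrays biological replicates but do not say in so many words that each is a different animal, so the p-values measure the spread between these samples. Groups were taken from the source labels and batches from the descriptions, which name 2 batches.

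The deposited scanner table holds, per the file headers, a mean bead intensity for 25697 probes on a linear scale with no normalization recorded. The same deposited table gives a detection p-value for each probe and array, per the file headers. Bead standard errors and bead numbers in that table were read only as checks. The authors' processed table holds log2 values of 12980 probes, and its scale was found here by comparison with the scanner values, since no header states it. Each of the 31 scanner columns correlated best with its own processed column, and the correlation of all values with the values normalized here was 0.997. Every processed column had a median of 8.65, so the arrays had been scaled to each other, and no centring of genes was seen. The processed table held probes with a detection p-value under 0.05 on at least 21 arrays, while the other probes reached at most 20. It had 31 empty cells, 1 per array, which fell in 14 probes. Limma is named in the submitters' processing notes. The scanner software, the batch correction and the annotation behind the processed values are not given in the sources used here. Batch accounted for 83.0% of component 1 in the values normalized here and for 4.16% in the processed values.

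Probe names came from annotation listed for the probes of the processed table. They were updated through a RefSeq gene table of assembly GRCm38.p6, which also gave the chromosomes. 12250 probes had 1 gene symbol and 0 had several. 5 symbols were updated and 1 probe was not matched in the gene table. A probe without a listed name is called unnamed, which does not mean that it has no gene. Probes detected on too few arrays for the processed table, such as ILMN_1241001, lack a name here. A gene counts as measured only if it has a named probe, so a gene not measured may still have a probe on the array.

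The scanner intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3. Background was inferred from the detection p-values because the table has no control probes, the offset was 16, and quantile normalization and log2 followed. Probes with a detection p-value under 0.05 on at least 7 arrays were kept, which left 14989. A gene with several probes was represented by the probe of highest mean over all arrays, which applied to 2363 genes. This left 8973 named genes and 2739 unnamed probes, 11712 tests per comparison.

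All 31 arrays entered a single limma fit with group and batch as terms, and 6 contrasts between groups were tested with the moderated, two-sided test and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of single genes are from this limma test unless stated otherwise, intervals are 95% intervals of the fit, and SE is the fit's standard error. Group levels are means of log2 signals before any batch correction. For a probe undetected on all arrays of a group, the fold is a lower bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among detected probes.

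Named genes followed a rule. They were the 12 largest rises and the 12 largest falls past the threshold in each comparison, the 5 of smallest p where fewer than 5 passed, list members past the threshold over all genes or over the list alone, and Xist, Kdm6a, Kdm5c, Eif2s3x, Ddx3x, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the labels. Of these check genes, Ddx3y, Eif2s3y and Kdm5d had no named probe among those tested, and they are not analysed here. Other members of a list are named as examples of it.

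24 gene lists were written for this tissue. They are X escape genes, Y-linked genes, steroid hormone signalling, dimorphic genes of the BNST and preoptic area from earlier work, neuropeptides and receptors, GABA, glutamate and monoamine signalling, immediate early genes, the circadian clock, glucocorticoid and stress response, heat shock, and markers of astrocytes, oligodendrocytes, microglia, endothelium and pericytes, choroid plexus and ventricle, meninges, striatal, thalamic, cortical and hippocampal, and septal neurons, blood and pituitary. 22 lists had at least 3 measured members and were tested with camera of limma at a preset correlation of 0.01, with adjustment over the lists of a comparison. The test was repeated with a correlation estimated from the residuals. A list mean per array is the mean over members of the log2 deviation from each gene's mean over all arrays, after removal of the fitted batch effect.

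The feminization score used 50 random halvings of the XX females and XY males within batches. In each, limma on 1 part picked the 100 of 8663 autosomal genes with the smallest p for the difference between the sexes. The score of an array outside that part is the mean over these genes of the signed log2 difference from the held-out XY males, averaged over halvings, on values with the fitted batch effect removed. The plan scaled the score so that held-out XX females had the value 1. Held-out XX females lay below held-out XY males in 12 of the 50 halvings, so that this scaling was not usable and the score is given in log2 units. The plan also named 100000 resamples, and all 5040 or 2520 relabellings within batches were enumerated instead, as an exact two-sided permutation test. The shift of X-linked genes outside the escape list used camera, and the agreement of the fold changes of XXY males and XX females against the shared XY males used Pearson's correlation across genes with simulated unchanged groups beside it.

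Groups, tests, gene lists and the alternative settings were fixed before the data were examined. The settings covered the normalization, the processed values, the filter on dim probes, the handling of batch, array weights, the variance prior, the choice of probes, the arrays in the fit and leaving out each array in turn. A different batch for array XX male 6, a block by the numbers in the titles, the X escape list without Xist, and leaving out each array in turn for the gene lists and for each named difference were added afterwards.

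The steps were tested on simulated data with 200 changed genes among 11712 per comparison. For XXY against XY males, 22% of 50 genes changed by 0.25 on the log2 scale were recovered, 72% of those changed by 0.5, 96% at 1 and 100% at 2, with 9 false calls. These rates hold for 200 changed genes with noise drawn independently per gene. With as few genes past the threshold as in the real comparisons the adjustment is stricter, so they can overstate what these data detect. The score of XXY against XY males gave 0.37 with an exact p of 0.000397, the smallest these relabellings can give, when XXY males were made to share a difference of 0.5 in 200 of 8663 genes with XX females. With no simulated difference the same test gave -0.017 with an exact p of 0.0321, and with the difference given to XX females alone it gave -0.02 for XXY males with an exact p of 0.0143. In 60 further simulations without a difference, p-values under 0.05 arose in 8.33% for XXY males, 13.3% for XX females and 5% for XX males, so the exact p of the score tends to be too small. Between 12939 and 14397 probes were detected per array, and the number of arrays limits the precision of the values. Figures were drawn with matplotlib 3.10.9.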

Results

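The arrays measured transcripts in tissue of the BNST and preoptic area, forebrain regions with known sex differences, of MF1 mice aged 152 days from a model of Klinefelter syndrome. In this model Sry, the testis-determining gene, is carried apart from the Y chromosome, so that XX animals with testes can be set beside XX animals with ovaries. The groups were 8 XX females, 7 XX males, 8 XXY males and 8 XY males. By the descriptions, batch 1 held 5 arrays of each group, and batch 2 held 3 of each group except the XX males, with 2. The question put by the series is whether the feminized partner preference of XXY males has a counterpart in gene expression.

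Between 12939 and 14397 of the 25697 probes were detected per array, or 50.35% to 56.03%. Correlations between arrays lay between 0.960 and 0.991. Component 1 held 32.0% of the variance and separated the batches, with array XX male 6 at 27.7, above the lowest array of batch 2 at 20.4, although its description names batch 1. The other arrays of batch 1 reached at most -10.8.

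**Figure D1:**
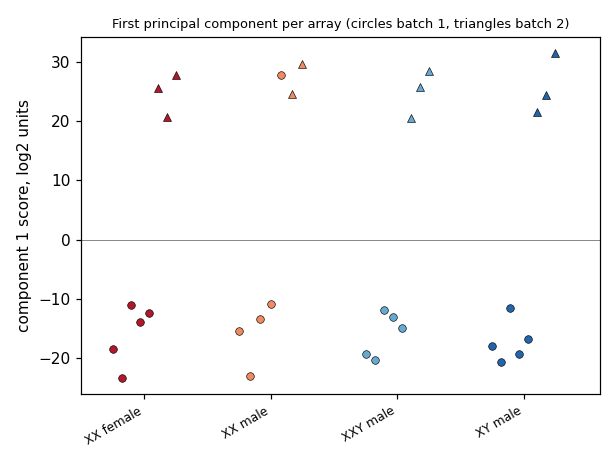
Score of each array on the first principal component (log2 units, vertical axis) by group, with circles for batch 1 and triangles for batch 2. Array XX male 6, at 27.7, is the only circle among the triangles, which start at 20.4.

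The comparison of XXY males with XY males asks what a second X chromosome changes in males with testes and a Y chromosome. Xist (ILMN_3022688), the RNA that coats the inactive X chromosome, was detected in 8 of 8 XXY males and in 0 of 8 XY males. Its log2 signal was 7.62 ± 0.63 (SD, n = 8) against 4.81 ± 0.29 (n = 8), a rise of at least 4.19-fold (adjusted p = 9.02e-07). Eif2s3x (ILMN_2649129), an X-linked subunit of a translation initiation factor, rose 1.55-fold (95% interval 1.41 to 1.71, adjusted p = 1.09e-06), from 10.79 ± 0.15 to 11.43 ± 0.13 (n = 8 each). Kdm6a (ILMN_2447456), an X-linked histone demethylase, rose 1.39-fold (1.23 to 1.57, adjusted p = 0.0203), and X-linked Pbdc1 (ILMN_1257485) rose by 0.37 on the log2 scale (SE 0.0648, adjusted p = 0.00876). Unnamed probes ILMN_3159435, by 1.97, and ILMN_2764607, by 0.52, completed the 6 of 11712 genes past the threshold, all of them higher. At an unadjusted p under 0.05 there were 322 genes, where chance gives 586.

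Within batch 1 and batch 2, the log2 differences were 0.69 and 0.55 for Eif2s3x, 0.45 and 0.51 for Kdm6a, and 0.37 and 0.38 for Pbdc1. Xist signal differed by 2.54 and 3.23, set against XY males at background, so that these are no fold sizes. Ddx3x, an X-linked RNA helicase, differed by 0.27 and Kdm5c, another X-linked histone demethylase, by 0.13, neither past the threshold. Uty, the only named Y-linked gene tested, differed by 0.01. Its probe was also detected on 7 of 8 XX female arrays, so it does not separate carriers of a Y. Kiss1, which encodes the kisspeptin peptides that drive gonadotropin release, differed by 0.18 (95% interval -0.19 to 0.56, adjusted p = 1), and Trim59, a member of a family of ubiquitin ligases, by 0.07. The Kdm6a call was lost without a batch term (adjusted p = 1) and with batch as a random block (0.337), over a range of 0.0054 to 1 across settings, and without any of XXY males 1, 4, 6 and 8 and XY males 3, 6 and 8 (0.0561 to 0.0706). The ILMN_2764607 call was lost with cyclic loess (adjusted p = 0.0511), with no filter on dim probes (0.0518) and without a batch term (0.178), over a range of 0.0162 to 0.999, and without any 1 of 12 arrays, XXY males 2, 3, 4, 5, 6 and 8 and XY males 1, 3, 4, 5, 6 and 7 (0.0631 to 0.138). Without background correction the Xist signal difference was 1.26, and other probes gave 1.33 for Xist, 0.43 (SE 0.0955, adjusted p = 0.183) for Kdm6a and 0.15 (SE 0.128, adjusted p = 1) for Pbdc1, so that the Kdm6a and Pbdc1 calls rest on 1 probe each. The other Kdm6a probe was close in size to the called one, at 0.47, and the other Pbdc1 probe was not.

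Among the gene lists, the X escape genes, which are transcribed from the inactive X, rose by a median of 0.37 (adjusted p = 1.46e-25, and adjusted p = 5.24e-10 with an estimated correlation), with 4 of 7 members past the threshold over all genes and 4 adjusted over the list alone. Without Xist, set against signal at background, the other 6 members had a mean of 0.35 (adjusted p = 6e-17, and adjusted p = 4.44e-08 with an estimated correlation). With Xist the mean signal difference was 0.70 in both batches. The meningeal markers were higher by a mean of 0.61 in 7 of 7 members (adjusted p = 0.00141), but adjusted p = 0.497 with an estimated correlation. Their examples include Slc6a13, a GABA and taurine transporter, at 0.90 (SE 0.646), and Lum, a matrix proteoglycan, at 0.69 (SE 0.403), and batches 1 and 2 gave 0.52 and 0.76. The blood markers were higher by 0.39 in 3 of 3 (adjusted p = 0.0138, and adjusted p = 0.473 with an estimated correlation), with Alas2, an enzyme of heme synthesis, at 0.61 (SE 0.269) and list means of 0.43 and 0.32 by batch, and the call was lost without any of XXY male 3 and XY males 1, 4 and 6 (adjusted p from 0.0537 to 0.11). The microglia markers were higher by 0.15 in 9 of 11 (adjusted p = 0.00483, and adjusted p = 0.311 with an estimated correlation), at 0.11 and 0.22 by batch. Adjusted over the list alone 2 of them passed, the complement genes C1qb at 0.49 (SE 0.157) and C1qc at 0.49 (SE 0.159), and over all genes 0. Beside these 3 lists stands the spread of the meningeal means, which lay above 0 in 5 of 8 XXY males, 3 of 8 XY males, 3 of 8 XX females and 3 of 7 XX males.

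Thalamic neuron markers were lower by a mean of -0.28 in 9 of 10 members (adjusted p = 0.036, and adjusted p = 0.699 with an estimated correlation), with Prkcd, a protein kinase C, at -0.75 (SE 0.566) and Tcf7l2, a transcription factor, at -0.51 (SE 0.376). Batches 1 and 2 gave -0.10 and -0.57. The call was lost with the submitters' values (adjusted p = 0.087) and without any of XXY males 2, 3 and 8 and XY males 4, 5, 6 and 8 (0.11 to 0.611), and the mean was -0.16 without XXY male 2, -0.18 without XXY male 8, -0.15 without XY male 5 and -0.42 without XY male 1. The striatal neuron markers had a mean of -0.13, negative in 9 of 10 (adjusted p = 0.0438, and adjusted p = 0.699 with an estimated correlation), but the sign turned between batches, at -0.27 and 0.11. XY male 2 alone had a list mean of 1.63, while the other XY males lay between -0.33 and -0.04 and the XXY males between -0.35 and -0.0021 (exact permutation p = 0.957). Without XY male 2 the difference turned to 0.11 (adjusted p = 0.6), and the call was also lost without any of XXY males 3, 4, 5, 7 and 8 (0.0508 to 0.122), with XX male 6 counted in batch 2 (0.051) and without XX male 6 (0.053). Neuropeptides and receptors had a mean of 0.05, positive in 31 of 45 (adjusted p = 0.0483, and adjusted p = 0.699 with an estimated correlation), and the sign turned here too, at -0.04 and 0.20. The call was lost with the submitters' values (adjusted p = 0.101), with XX male 6 counted in batch 2 (0.051), without it (0.0576) and without any of XXY males 2, 3, 6, 7 and 8 and XY males 2, 5, 6, 7 and 8 (0.0595 to 0.724). Without XY male 5 the mean turned to -0.02, and it was 0.08 without XXY male 3, 0.08 without XXY male 5, 0.02 without XXY male 6, 0.01 without XXY male 8 and 0.09 without XY male 3. Mc4r, the melanocortin receptor of appetite control, differed by 0.30 (SE 0.102) and did not pass over the list alone.

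The other 15 lists did not pass, with adjusted p from 0.26 to 0.985. Mean differences were -0.03 for steroid hormone signalling (median 0.0015), 0.04 for dimorphic genes of the BNST and preoptic area, -0.04 for glutamate transmission, -0.02 for monoamine signalling, -0.04 for immediate early genes, -0.06 for the circadian clock and -0.02 for the glucocorticoid and stress response. They were 0.02 for heat shock, 0.01 for astrocytes, -0.00016 for oligodendrocytes, 0.02 for endothelium and pericytes, 0.0089 for choroid plexus and ventricle, -0.07 for cortical and hippocampal neurons (median 0.03) and 0.17 for septal neurons (median -0.04). In GABA transmission the mean was -0.07 and the median 0.04, with Gabrd, a subunit of extrasynaptic GABA receptors, at -1.03 (SE 0.562). Across the 31 arrays Gabrd correlated at 0.791 with Prkcd of the thalamic list, a pair not in the plan. Mean and median thus differed in sign in the steroid, cortical, septal and GABA lists. Over all comparisons the mean, median and test differed in sign in 21 of 132 list tests, of which 0 passed. By exact permutation of the list means, 3 of the 132 passed, those of the X escape genes against XY males (adjusted p = 0.00873 each). Cux2, a transcription factor of upper cortical neurons, passed adjusted over the list alone at -0.44 (SE 0.13) and not over all genes. Lists of Y-linked genes and pituitary markers had 1 measured member each, Uty and Pomc, and were not tested. Pomc, the precursor of melanocortins, differed by -0.04 (SE 0.696).

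**Figure D2:**
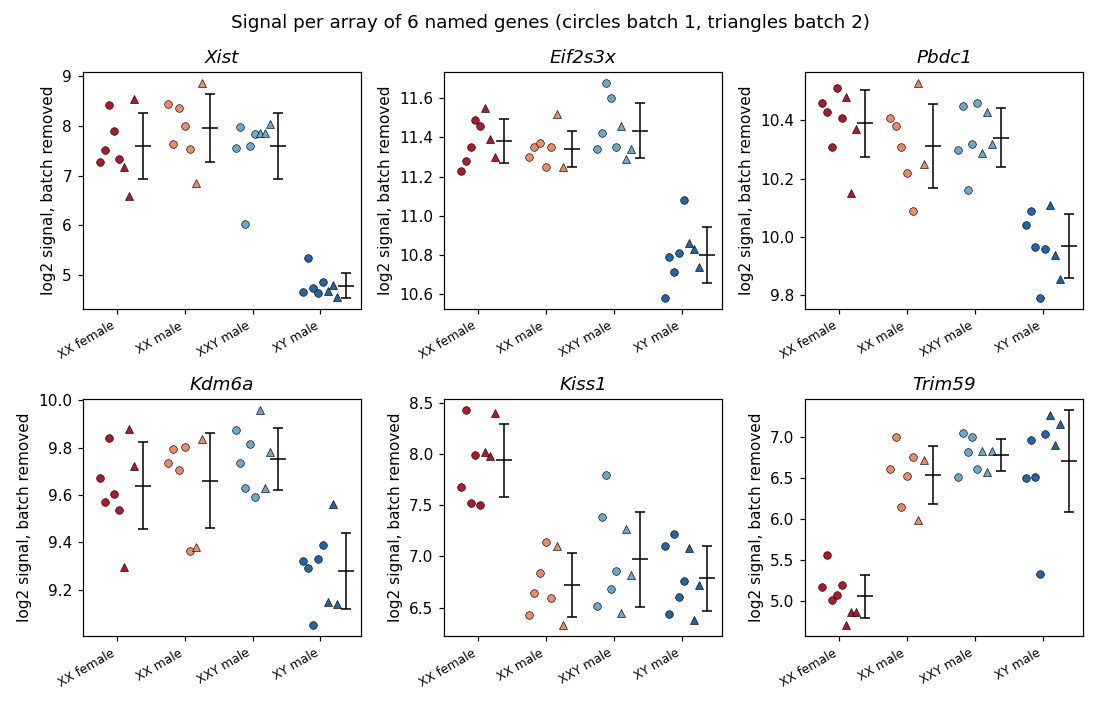
Log2 signal after removal of the fitted batch effect (vertical axis) of 6 genes on each array by group, with circles for batch 1, triangles for batch 2 and bars for the mean ± SD. Xist, Eif2s3x, Pbdc1 and Kdm6a are lower in XY males as a group, while Kiss1 is higher and Trim59 lower in XX females.

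The comparison of XX females with XY males gives the reference sex difference. Kiss1 (ILMN_2735829, chromosome 1) rose 2.23-fold in XX females (95% interval 1.72 to 2.88, adjusted p = 0.000826), at 7.94 ± 0.35 (SD, n = 8) against 6.79 ± 0.32 (n = 8). Trim59 (ILMN_2993661, chromosome 3) was detected in 0 of 8 XX females and 7 of 8 XY males, at 5.07 ± 0.34 against 6.73 ± 0.58, and was at least 2.29-fold lower in females (adjusted p = 3.5e-06). X-linked Xist was higher at least 4.19-fold (adjusted p = 2.25e-07), Eif2s3x by 0.58 (SE 0.0676, adjusted p = 3.5e-06) and Pbdc1 by 0.42 (SE 0.0648, adjusted p = 0.000634). Unnamed probe ILMN_2899599 was 21.7-fold lower (adjusted p = 8.25e-15) and ILMN_1241001 at least 3.97-fold lower (adjusted p = 3.68e-13), and another unnamed probe at least 1.81-fold lower. The 8 genes past the threshold were 4 higher and 4 lower, and 496 had an unadjusted p under 0.05.

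By batch, Kiss1 differed by 1.00 and 1.41, Eif2s3x by 0.57 and 0.60 and Pbdc1 by 0.46 and 0.36, while another Pbdc1 probe gave 0.07 (SE 0.128, adjusted p = 1) over both. Signal differed by -1.27 and -2.30 for Trim59 and by 2.83 and 2.75 for Xist, set against a group at background, so that these are no fold sizes. Without background correction the signal differences were 0.66 for Kiss1, -0.65 for Trim59 and 1.26 for Xist.

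X escape genes were higher by a median of 0.42 (adjusted p = 4.09e-20, and adjusted p = 6.9e-09 with an estimated correlation), with mean signal differences of 0.76 and 0.59 by batch. Without Xist the mean was 0.34 (adjusted p = 4.95e-13, and adjusted p = 5.75e-07 with an estimated correlation). Over all genes 3 of 7 passed, and adjusted over the list alone 5, which added Kdm6a at 0.36 and Ddx3x at 0.49. The glucocorticoid and stress response was higher by 0.30 in 13 of 13 members (adjusted p = 0.000543, and adjusted p = 0.473 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor, at 0.92 (SE 0.354) and batch values of 0.42 and 0.10. Without XX female 8 the mean was 0.16 and the call was lost (adjusted p = 0.161), and without XX female 5 it was 0.19. XX females 1, 5 and 8 had list means of 0.57, 0.97 and 1.11, while the other 5 lay between -0.43 and 0.02, within the range of the XY males from -0.48 to 0.68 (exact permutation p = 0.265). Immediate early genes, induced by neuronal activity, were higher by 0.18 in 11 of 13 (adjusted p = 0.00539, and adjusted p = 0.183 with an estimated correlation), led by Fos at 0.77 (SE 0.263), and the list gave 0.18 and 0.19 by batch. Heat shock genes were higher by 0.12 in 10 of 10 (adjusted p = 0.00539, and adjusted p = 0.243 with an estimated correlation), with the chaperone Hsp90aa1 at 0.35 (SE 0.148) and list means of 0.16 and 0.06 by batch. Oligodendrocyte markers had a mean of -0.15, negative in 10 of 10 (adjusted p = 0.00262, and adjusted p = 0.473 with an estimated correlation), with the myelin gene Mog at -0.25 (SE 0.116) and list means of -0.05 and -0.30 by batch. In these 4 lists 0 members passed adjusted over the list alone. The other 17 lists had adjusted p from 0.0588 to 0.895.

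XX males and XY males both have testes and differ in their sex chromosomes. Xist was detected in 7 of 7 XX males, at 8.00 ± 0.69 (SD, n = 7), at least 5.46-fold above the XY males (adjusted p = 4.13e-08). Eif2s3x rose 1.46-fold (adjusted p = 3.71e-05), Pbdc1 by 0.35 (SE 0.0672, adjusted p = 0.0265) and ILMN_3159435 2.54-fold (adjusted p = 0.00206). ILMN_2899599 was 22.8-fold lower (adjusted p = 1.44e-14), ILMN_1241001 at least 3.98-fold lower (adjusted p = 2.31e-12), and a further unnamed probe at least 1.81-fold lower. These 7 genes were 4 higher and 3 lower, with 659 at an unadjusted p under 0.05. Kiss1, with XX males at 6.73 ± 0.32 (n = 7), and Trim59 did not pass.

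By batch, the differences were 0.53 and 0.57 for Eif2s3x and 0.32 and 0.42 for Pbdc1, and 3.14 and 3.18 for Xist signal, set against XY males at background and so no fold sizes. Another Pbdc1 probe had the opposite sign, at -0.22 (SE 0.133, adjusted p = 0.897). The Pbdc1 call was lost with array XX male 6 counted in batch 2 (adjusted p = 0.104) and without a batch term (0.169), over a range of 0.0135 to 1 across settings, and without any of XX males 1, 2, 3 and 7 and XY males 3, 4, 5, 7 and 8 (0.0605 to 0.117). Without background correction the Xist signal difference was 1.497.

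Only the X escape list passed of 22, with a median of 0.38 (adjusted p = 1.32e-14, and adjusted p = 1.77e-07 with an estimated correlation) and mean signal differences of 0.72 and 0.74 by batch. Without Xist the mean was 0.31 (adjusted p = 1.28e-08, and adjusted p = 2.19e-05 with an estimated correlation). Over all genes 3 of its 7 members passed and adjusted over the list alone 5, with Kdm6a at 0.38 and Ddx3x at 0.60. The other 21 lists had adjusted p from 0.234 to 0.971. In the lists of 1 member, Uty differed by -0.35 (SE 0.134) and Pomc by -1.67 (SE 0.722), neither past the threshold over all genes.

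XXY males and XX males both have testes and at least a pair of X chromosomes, and differ in the Y. The genes past the threshold were 3 unnamed probes, all higher in XXY males, with ILMN_2899599 at 19.5-fold (adjusted p = 5.91e-14), ILMN_1241001 at least 3.95-fold (adjusted p = 2.51e-12) and another at least 1.81-fold. Xist differed by -0.37 (SE 0.293), Eif2s3x by 0.09 (SE 0.0702) and Kdm6a by 0.09 (SE 0.0911), none past the threshold. Among those of smallest p, Akap8l, an anchoring protein of protein kinase A, differed by -0.35 (adjusted p = 0.727). An unnamed probe, detected in 0 of 8 XXY males, was at least 1.11-fold lower in them (adjusted p = 0.728). There were 767 genes with an unadjusted p under 0.05. Uty differed by 0.36 (SE 0.134) and Pomc by 1.63 (SE 0.722), each alone in its list.

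Striatal neuron markers had a mean of -0.34, negative in 10 of 10 (adjusted p = 0.0129, and adjusted p = 0.597 with an estimated correlation), with Ppp1r1b, which encodes a dopamine-regulated phosphatase inhibitor, at -0.78 (SE 0.434) and the dopamine receptor Drd2 at -0.42 (SE 0.201). Batches 1 and 2 gave -0.34 and -0.35, and without XX male 8 the call was lost at -0.26 (adjusted p = 0.212). Immediate early genes had a mean of -0.20 in 13 members (adjusted p = 0.0342, and adjusted p = 0.512 with an estimated correlation), with Egr4, a transcription factor, at -0.61 (SE 0.234), and -0.19 in both batches. That call was lost without any of XX males 2, 3 and 8 and XXY males 1, 6 and 7 (adjusted p from 0.0713 to 0.212). The mean was -0.17 for cortical and hippocampal markers, negative in 7 of 7 (adjusted p = 0.0342, and adjusted p = 0.512 with an estimated correlation), with Camk2a, a synaptic kinase subunit, at -0.27 (SE 0.119) and list means of -0.02 and -0.49 by batch. This call was lost with the submitters' values (adjusted p = 0.0521) and without any of XX males 2, 3 and 8 and XXY males 3, 6, 7 and 8 (0.055 to 0.313), with a mean of -0.04 without XX male 8. The mean was 0.13 for microglia markers (adjusted p = 0.0342, and adjusted p = 0.534 with an estimated correlation), at 0.0035 and 0.40 by batch, beside a meningeal mean of 0.44 (adjusted p = 0.0895) that turned sign between batches, at -0.22 and 1.78. The microglia call was lost without any of XX males 2, 3, 7 and 8 and XXY males 2, 6, 7 and 8 (adjusted p from 0.055 to 0.23). Adjusted over the list alone, 0 members of these lists passed, and the other 18 lists had adjusted p from 0.0837 to 0.924.

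XX females and XX males share their sex chromosomes and differ in gonads and in the Sry transgene. Kiss1 rose 2.33-fold in females (95% interval 1.78 to 3.04, adjusted p = 0.00244), at 7.94 ± 0.35 (SD, n = 8) against 6.73 ± 0.32 (n = 7). Trim59, detected in 0 of 8 females and 7 of 7 XX males, was at least 2.05-fold lower in females (adjusted p = 0.000406), and an unnamed probe at least 1.30-fold lower (adjusted p = 0.0478). These 3 genes were 1 higher and 2 lower, with 788 at an unadjusted p under 0.05. Smad2, which carries signals of the TGF-beta family, differed by 0.55 (adjusted p = 0.473). The signal of another unnamed probe differed by -0.37 (adjusted p = 0.473). That probe was detected in 0 of 8 females and 4 of 7 XX males, so that this is no fold size. X-linked Xist, at -0.36, and Eif2s3x, at 0.04, did not pass.

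By batch, Kiss1 differed by 1.10 and 1.42, and without background correction by 0.69. Trim59 signal differed by -1.41 and -1.54, and by -0.56 without background correction, set against females at background, so that these are no fold sizes. The call of the unnamed probe was lost with array XX male 6 counted in batch 2 (adjusted p = 0.0566), with no filter on dim probes (0.092), with batch as a random block (0.136) and without a batch term (1), over a range of 0.0113 to 1 across settings. It was also lost without any 1 of 11 arrays, XX females 1, 2, 3, 4, 6, 7 and 8 and XX males 5, 6, 7 and 8 (0.0634 to 0.18). No list of 22 passed, with adjusted p from 0.074 to 0.791, and adjusted over the list alone 1 neuropeptide gene passed, Kiss1.

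XXY males and XX females differ in gonads, in the Y and in the Sry transgene. Kiss1 was 1.96-fold lower in XXY males (adjusted p = 0.0183), at 6.97 ± 0.47 (SD, n = 8) against 7.94 ± 0.35 (n = 8). Trim59, detected in 8 of 8 XXY males and 0 of 8 females, was at least 2.40-fold higher (adjusted p = 2.09e-06). ILMN_2899599 was 18.5-fold higher (adjusted p = 3.48e-14), ILMN_1241001 at least 3.95-fold, ILMN_3159435 2.39-fold (adjusted p = 0.00408) and a further unnamed probe at least 1.81-fold. Of these 6 genes 5 were higher and 1 lower, and 627 had an unadjusted p under 0.05. Xist did not pass, at 7.62 ± 0.63 and 7.62 ± 0.68 (n = 8 each).

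By batch, Kiss1 differed by -0.78 and -1.29, and without background correction by -0.56. Trim59 signal differed by 1.60 and 1.94, and by 0.66 without background correction, set against females at background, so that these are no fold sizes. The Kiss1 call was lost among genes detected on all arrays (adjusted p = 0.0685, over a range of 0.00599 to 1 across settings). It was also lost without any 1 of 8 arrays, XX females 2, 6 and 8 and XXY males 1, 4, 5, 6 and 8 (0.0524 to 0.0763).

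With the preset correlation 10 of 22 lists passed, and with an estimated correlation 0. The glucocorticoid and stress response was lower in XXY males by a mean of -0.32 in 13 of 13 members (adjusted p = 0.000459, and adjusted p = 0.323 with an estimated correlation), with Cdkn1a at -1.04 (SE 0.354) and list means of -0.41 and -0.18 by batch. Without XX female 5 the mean was -0.21, and without XX female 8 it was -0.18. XX females 1, 5 and 8, at 0.57, 0.97 and 1.11, lay above the XXY males, which ranged from -0.32 to 0.07, and the other 5 lay between -0.43 and 0.02 (exact permutation p = 0.205). Immediate early genes had a mean of -0.23 (adjusted p = 0.000768, and adjusted p = 0.0896 with an estimated correlation), with Fos at -0.80 (SE 0.263) and list means of -0.19 and -0.28. Heat shock had -0.10 (adjusted p = 0.0165, and adjusted p = 0.323 with an estimated correlation), at -0.13 and -0.06 by batch, and thalamic markers -0.38 in 10 of 10 (adjusted p = 0.00498, and adjusted p = 0.508 with an estimated correlation), at -0.29 and -0.53. The heat shock call was lost without any of XX females 4 and 6 and XXY males 1 and 7 (adjusted p from 0.0514 to 0.179), and the thalamic call without XXY male 2, at -0.26 (adjusted p = 0.0508).

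The meningeal markers were higher in XXY males by 0.71 in 7 of 7 (adjusted p = 0.00309, and adjusted p = 0.323 with an estimated correlation), with a list mean of 0.03 in batch 1 and 1.85 in batch 2. Blood markers gave 0.40 (adjusted p = 0.0159, and adjusted p = 0.323 with an estimated correlation), at 0.38 and 0.43 by batch and at 0.30 without XXY male 3, where the call was lost (adjusted p = 0.0859), and microglia markers 0.16 (adjusted p = 0.00466, and adjusted p = 0.252 with an estimated correlation), at 0.11 and 0.25. Endothelial and pericyte markers gave 0.20 (adjusted p = 0.0105, and adjusted p = 0.252 with an estimated correlation), at 0.19 and 0.23, with the smooth muscle actin Acta2 at 0.64 (SE 0.298). Oligodendrocyte markers gave 0.15 in 10 of 10 (adjusted p = 0.00466, and adjusted p = 0.34 with an estimated correlation), at 0.06 and 0.29. The dimorphic genes were higher by 0.13 in 12 of 15 (adjusted p = 0.0162, and adjusted p = 0.323 with an estimated correlation), at 0.02 and 0.32, with vasopressin, Avp, at 0.71 (SE 0.365) and the exocytosis gene Sytl4 at 0.35 (SE 0.132). This call was lost without any of XX females 7 and 8 and XXY males 2, 3 and 8 (adjusted p from 0.0508 to 0.0875). Adjusted over the list alone 1 microglia gene passed, Aif1, an actin-binding protein of microglia, at 0.32 (SE 0.0952), as did Cux2 of the cortical list at -0.40 (SE 0.13) and Kiss1 of the neuropeptides. The other 12 lists had adjusted p from 0.21 to 0.898.

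**Figure D3:**
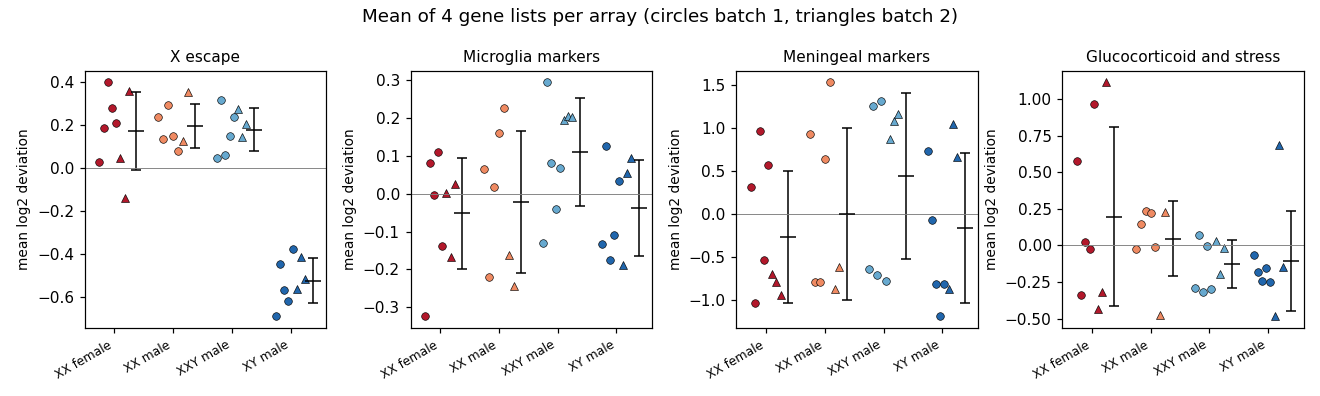
Mean log2 deviation of 4 gene lists from the mean of all arrays (vertical axis) on each array by group, with circles for batch 1, triangles for batch 2 and bars for the mean ± SD. The X escape mean, which includes Xist, is lowest in XY males, and meningeal means lie above 0 in 5 of 8 XXY males and 3 of 8 XY males.

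The feminization score asks whether autosomal genes of XXY males lean toward the female side of the sex difference, with a score above 0 on that side. It averaged 0.036 ± 0.033 (SD, n = 8) in XX females, -0.039 ± 0.066 (n = 8) in XXY males, -0.014 ± 0.054 (n = 7) in XX males and 2.3e-05 ± 0.07 (n = 8) in XY males. XXY males differed from XY males by -0.040 (exact permutation p = 0.258), with 3 of 8 above 0, and by -0.059 (exact p = 0.238) and -0.0074 (exact p = 1) in batches 1 and 2. XX males differed by -0.015 (exact p = 0.658), at -0.051 and 0.058 by batch, and by 0.0046 without XY male 5. With sex-linked genes kept in, the difference was 0.00345 (exact p = 0.918) for XXY males and 0.0308 (exact p = 0.358) for XX males. Held-out XX females did not stand apart from XY males, at 0.036 (exact p = 0.206), with 0.0079 (exact p = 0.849) in batch 1 and 0.083 (exact p = 0.1, the smallest possible there) in batch 2. Fitted in batch 1 alone, the difference turned to -0.052 (exact p = 0.413). With no effect simulated, the XXY score difference had an SD of 0.042. XX females differed by 0.077 (exact p = 0.019) with sex-linked genes kept in, by 0.081 (exact p = 0.0234) with 50 genes and by 0.0092 (exact p = 0.712) with 200 genes. These stand beside an SD of 0.052 with no effect simulated, where 13.3% of the p-values lay under 0.05. A score on which XX females do not stand apart from XY males cannot decide whether XXY males are feminized.

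**Figure D4:**
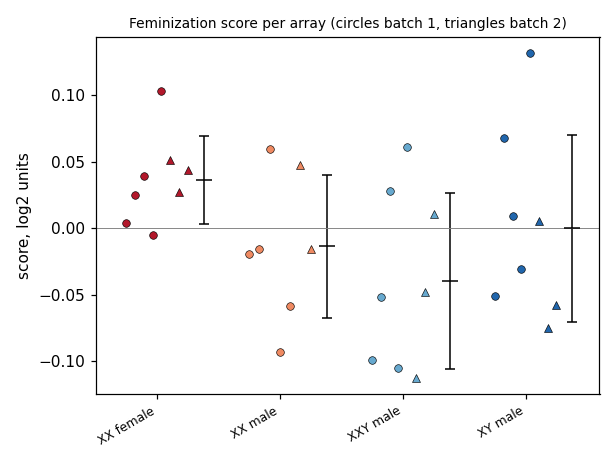
Feminization score of each array (log2 units, vertical axis) by group, with circles for batch 1, triangles for batch 2 and bars for the mean ± SD. The groups overlap, and 7 of 8 XX females, 3 of 8 XXY males and 2 of 7 XX males lie above 0.

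Across 8663 autosomal genes, which are not independent replicates, the log2 differences of XXY males and of XX females from the shared XY males correlated at 0.301. Simulated groups with no effect against the same controls gave a mean of 0.50 (0.0953 to 0.762), and 94 of 100 were as high. The covariance was 0.00504 against 0.0104 in the simulations. With disjoint parts of the XY males as controls, the correlation was -0.184 ± 0.129 (SD over 50 halvings).

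X-linked genes outside the escape list, 301 in number, were higher than autosomal genes by 0.012 in XXY against XY males (p = 0.552, and p = 0.593 with an estimated correlation), at 0.016 and 0.0059 by batch. In the other comparisons the shift was 0.0048 for XX females against XY males, -0.025 for XX males against XY males, 0.037 for XXY against XX males, 0.030 for XX females against XX males and 0.0073 for XXY males against XX females. Adjusted over the 6 comparisons, the smallest p was 0.0646 with the preset correlation and 0.124 with an estimated correlation.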

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

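The tests of the batch label, the processed values and the hybridization of XX male 6, of chromosome 3 and gonadal effects for Trim59, and of the meningeal genes were chosen after the result was seen. The tests of RNA of another group, of microglia beside meninges and blood, and of other splits were set before. For RNA of another group, Trim59 was in no planned list, and ILMN_2899599 was added to that test later. Both were known only from differences in these arrays.

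In 5 of 92 groups of values 1 array lay far from the others of its group, where chance gives about 1 in 20. Xist, with the batch effect removed, was 6.02 in XXY male 3 (others 7.55 to 8.04) and 5.35 in XY male 2 (others 4.57 to 4.87). Trim59 was 5.33 in XY male 4 (others 6.49 to 7.26), and C1qc was 10.6 in XX female 2 (others 9.93 to 10.2). XX male 2 had 50.35% of probes detected (others 52.9% to 54.9%), and the arrays numbered 2 in all 4 groups had 50.35% to 51.5%.

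XX male 6 lay with the arrays of batch 2 although its description names batch 1. On an axis from batch 1 (0) to batch 2 (1) made from the other arrays it lay at 0.921, where batch 2 arrays lay between 0.761 and 1.15 and other batch 1 arrays between -0.338 and 0.18, and title number 6 is batch 2 in the 3 other groups. Its processed value lay at 0.159, within the -0.205 to 0.28 of the other arrays, so the submitters may have counted it in batch 2. On component 1 of the processed values, however, it lay at 25.4, outside the -19.2 to 18.2 of the other arrays. Batch accounted for 4.16% of that component. Its share of probes detected, 54.77%, lay within the 50.35% to 54.85% of the other XX males and gave no sign of poor hybridization. Its median signal was 228.8, against at most 185.9 in the other XX males, so other faults of the array stay open. RNA of another group was excluded by Trim59, Xist and ILMN_2899599. Trim59, detected in all 7 XX males, had signal 1.2 above the highest of the XX females. The females lay at background, so that this is no fold size. Xist of XX male 6 was 7.62 against at most 5.44 in XY males. In ILMN_2899599 no XX male overlapped the XXY males. Its median signal also lay among the arrays with title number 6, at 211.4 to 258.6. The title and the description of this array also carry different numbers. A batch label differing from the true batch is a candidate explanation, and no biological explanation was tested. The main fit, the exact permutations and the values by batch follow the description and count this array in batch 1. Values of XX males by batch may therefore mix batches.

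Trim59 was low in XX females against all 3 male groups. A candidate explanation is a stretch of chromosome 3 that differs between females and males, since in this model the Sry transgene sits on that chromosome. Without Trim59, 15 of 437 chromosome 3 genes (3.43%) and 95 of 8225 other autosomal genes (1.16%) had an unadjusted p under 0.01 between females and males (Fisher's exact p = 0.000391, though genes are not independent), with 7 of 80 near Trim59 and 8 of 357 on the rest of the chromosome. As many chromosome 3 genes arose in 6 of 100 splits of the arrays (highest other split 30), and by the limit of fewer than 5 set for this test that counted against the explanation, while as high a share of all such genes arose in 2 of 100. The reading was changed to undecided after the value of 6 was seen, because no value forbids the explanation, and with Trim59 differing by at most 0.244 between male groups, gonadal effects and the chromosome cannot be told apart where all males carry both Sry and testes.

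Meningeal, blood and microglia genes were higher in XXY males than in XY males, past the threshold with the preset correlation only. With an estimated correlation their adjusted p was 0.497, 0.473 and 0.311, and by exact permutation of the list means 0.886, 0.886 and 0.481, and the blood call was also lost without any of XXY male 3 and XY males 1, 4 and 6 (adjusted p from 0.0537 to 0.11). The meningeal genes moved together within groups and batches, with a mean correlation of 0.672 between genes, which unequal amounts of meninges would give. Amounts that differ by dissection or for another reason would both give it, so it does not favour either. The microglia difference of 0.147 (SE 0.077) was 0.105 (SE 0.0737) with the meningeal mean as a covariate and 0.095 (SE 0.0763) with the blood mean, which leaves meninges and blood open as its source. For the second X, the exact permutation p of the meningeal mean was 0.157, and the XX males, which also have a second X, differed from XY males by 0.17 (SE 0.478), a mean of opposite signs in the batches, at 0.73 and -1.03.

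Other splits of the same arrays, 100 per comparison with the real one included, were drawn without regard to batch. In each comparison fewer than 5 of them gave as many genes past the threshold. Against XY males the counted genes include Xist and other X-linked genes, which follow the number of X chromosomes. ILMN_2899599 and ILMN_1241001 separated groups with a Y from groups without it. Such genes can carry a count, so it does not speak for the remaining genes. For XXY against XY males the count was 6 (highest other split 4), reached in 1 split, for XX females against XY males 8 (1), in 1 split, and for XX males against XY males 7 (26), in 3 splits. A split with 26 genes points to a structure of the samples, and what its arrays share was not tested. For XXY against XX males the count was 3 (3), in 2 splits, for XX females against XX males 3 (1), in 1 split, and for XXY males against XX females 6 (3), in 1 split.

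For the number of gene lists past the threshold, fewer than 5 splits reached the real count only for XXY males against XX females. There 10 lists passed (highest other split 8), reached in 1 split. With an estimated correlation 0 of these 10 passed, and the lowest adjusted exact permutation p of a list mean there was 0.179. Chance was not excluded for XXY against XY males with 7 (10), in 8 splits, XX females against XY males with 5 (8), in 26, XX males against XY males with 1 (11), in 88, XXY against XX males with 4 (8), in 17, or XX females against XX males with 0 (8), in 100. Nor was it for the X-linked shift of 0.012 in XXY against XY males (highest other split 0.033), in 44 splits.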

How the results depend on the processing

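Counting XX male 6 in batch 2, leaving it out where it is not in the comparison, a block by the title numbers, the X escape list without Xist and leaving out each array in turn for the gene lists and for each named difference were chosen after seeing the data, and the other alternatives were set before.

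The count of genes stayed within 1.5 times its value in 13 of 16 alternatives for XXY against XY males, 14 for XX females against XY males, 14 for XX males against XY males, 14 for XXY against XX males, 13 for XX females against XX males and 15 for XXY males against XX females. XXY against XY males gave 3 genes in batch 1 alone, 0 in batch 2 alone (limma) and 3 with only the groups compared. In batch 2 alone XX males against XY males gave 4, and XX females against XX males gave 0 in either batch. These fits had fewer samples. The submitters' values, with 9692 genes tested, gave 5 for XX females against XY males and 1 for XXY against XX males. Genes detected on all arrays, 8499 in number, gave 3 for XX females against XY males, 2 for XX males against XY males, 0 for XXY against XX males, 1 for XX females against XX males and 0 for XXY males against XX females. That set cannot hold Xist, Trim59, ILMN_2899599, ILMN_1241001, ILMN_1224210 or ILMN_3159435, each undetected on some arrays. The submitters' values cannot hold ILMN_1241001 or ILMN_1224210, undetected in both groups without a Y. Lower counts in these 2 settings were therefore bound to follow. Leaving out 1 array in turn gave 4 to 6, 8 to 10, 6 to 8, 3 to 3, 2 to 4 and 5 to 7 genes in the order of the report.

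Of 33 named differences past the threshold, 21 of 21 tested passed with the submitters' values, 10 of 11 among genes detected on all arrays and 14 of 33 in batch 2 alone. Over the 10 alternatives run for them 0 of 296 turned direction and 254 passed, but the choice of probe was not among these, and another Pbdc1 probe turned direction for XX males against XY males (-0.22 against 0.35). With 1 array of the comparison left out in turn, 28 of the 33 passed throughout and 5 did not, which were Kdm6a and ILMN_2764607 for XXY against XY males, Pbdc1 for XX males against XY males, an unnamed probe for XX females against XX males and Kiss1 for XXY males against XX females.

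Of 27 list tests 3 passed with an estimated correlation, all of the X escape list. The submitters' values kept 24 of the 27, losing the neuropeptide and thalamic lists of XXY against XY males and the cortical list of XXY against XX males, and gave 3 others. Counting XX male 6 in batch 2 kept 25 and gave 4 others, and leaving it out kept 25 and gave 5 others, both losing the neuropeptide and striatal lists of XXY against XY males. All 27 passed without a batch term, with no filter on dim probes and with Xist left out of its list. With no filter the lists kept the same members, since the probes added have no name. With each of the 31 arrays left out in turn, 21 to 33 list tests passed. Of the 27, 14 passed without each array of their comparison and 13 were lost without at least 1. For these losses, and for the scores below, the cause was not tested.

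The score of XXY males turned to 0.00345 with sex-linked genes kept in, which adds genes that differ by sex chromosome, and ranged from -0.052 to -0.0221 with 1 array left out. That of XX males turned to 0.0308 with sex-linked genes and to 0.00458 without XY male 5, from a range of -0.0312 to 0.00458. The agreement of fold changes turned to -0.184 with disjoint parts of the XY males. The X-linked shift lay between 0.0059 and 0.028.

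A block by the numbers of the descriptions gave 6, 10, 7, 3, 3 and 7 genes, and by those of the titles 4, 11, 6, 3, 2 and 8. Arrays sharing a number had median correlations of 0.0741 and 0.1 (other pairs -0.0406 and -0.0452), and 19 of 45 and 20 of 42 pairs were over 0.1. The numbers were not taken to pair the samples, since no label names a shared run. However, 19 of 31 and 23 of 30 arrays correlated best with their own number, and no chance level was worked out for these counts. A shared run need not lift every pair, so shared handling stays open. The main fit, the permutations and the splits carry no block for it. Arrays with title number 2 had 50.35% to 51.5% of probes detected (others at least 52.15%), and those with number 6 a median signal of 211.4 to 258.6 (others at most 200.9). These values come from the data, and the columns of the scanner table also stand grouped by title number. A slide block was not run because no slides are named. Leaving out the filter moved nothing for the scores, the X-linked shift and the agreement. The probes it adds have no name and so no chromosome here, so this setting could not move these results. Signal close to background limits what a dim probe can show, and without background correction differences of dim genes such as Xist shrank.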

Other observations

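Hcrt and Pmch were picked after their values were seen.

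Hcrt and Pmch, neuropeptides of lateral hypothalamic neurons, varied widely between arrays, from 5.08 to 11.9 and from 8.60 to 14.3 on the log2 scale. The range within a group was 5.33 to 6.64 for Hcrt and 5.10 to 5.72 for Pmch.

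A test of whether each gene's difference depended on the batch found 0 genes with limma in each of the 6 comparisons, with 252 to 520 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.0893, for Psmc3ip between XX females and XX males.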
